A study of Sus scrofa with 36 samples.

How the data were processed

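Total RNA from the mammary gland of 36 pigs was labelled with biotin and hybridized to 1 porcine Affymetrix array per animal. The deposited values are probe set summaries that the authors normalized with RMA, per the labels. The version of RMA and the software are not given in the sources used here. The labels do not state the base of the logarithm. The deposited values were read as log2, because they ranged from 1.552 to 13.74 with nearly equal quantiles in all arrays, so every fold rests on that reading. The values were used as deposited, with no further normalization. The raw intensities were not analysed here.

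Groups were taken from the treatment labels: sham and 8 ovariectomized groups, with 4 pigs each. The design text states that each combination was given to 4 pigs, so arrays were treated as separate animals. The titles carry a letter from A to D for each animal of a group, and nothing in the labels used here says that a letter links animals of different groups. Positions on the genome and a genome build were not used here. The 20792 probe sets comprised 9149 with 1 gene symbol, 178 with several and 11465 with no symbol here, and 6360 genes were represented. A gene was represented by the probe set with the highest mean over all arrays among those with that symbol alone. Of the 9149 symbols, 9054 had a gene identifier found in the reference table, and 0 of these had another current symbol. Control probe sets were not analysed here, so RNA quality was not compared along transcripts. The 36 arrays were compared by their quantiles, their correlations and their principal components.

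Tests used limma 3.58.1 in R 4.3.3, with statmod 1.5.0. A linear model with 1 mean for each of the 9 groups was fitted to all 36 arrays (27 residual degrees of freedom), variances were moderated by eBayes (4.16 prior degrees of freedom), and p-values, two-sided, were adjusted by Benjamini and Hochberg over all probe sets within each comparison. An adjusted p under 0.05 was called. The 16 comparisons were B against sham, the average effects of estrogen, progesterone and haloperidol over the other factors, their 3 pairwise interactions and the interaction of all 3, each of 7 groups against B, and HEP against BEP. An interaction is given as the difference between the effects of 1 factor at the levels of the other, averaged over the remaining factor. Adjustment did not run across the 16 comparisons.

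The comparisons, the alternatives, the rule for named genes and 24 gene lists were fixed before the data were examined, except where the text says that a choice came after. In 8 comparisons named in full, the rule takes the 10 genes with the largest change in each direction among those called, leaving out symbols that start with LOC, and in the others the 3 largest. To these it adds up to 4 called members with the largest change from each list described, and 21 fixed genes whether or not they pass, of which 13 were measured under their symbol. Lists were tested with camera from limma, two-sided, with a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry. Adjustment ran over the 24 lists within a comparison. Of the 24 lists, 9 were measured at under 50% of their members, and some genes stand in more than 1 list. A list called with the preset correlation alone, meaning not by camera with an estimated correlation, is weaker evidence where its genes vary together between animals. Camera sets a list against all other genes and fry does not, and results of fry are given only where it is named. The score of a list is the mean of its genes after each was centred over the 36 arrays.

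The model was tested on simulated data with 200 changed probe sets among 20792. With a change of 1 on the log2 scale, 37.0% were recovered with 7 false calls in B against sham, 91.0% with 7 false calls for the average effect of estrogen, and 34.0% with 2 false calls for the interaction of estrogen with haloperidol. With a change of 2 these shares were 89.5%, 99.0% and 92.5%, with 9, 13 and 16 false calls. The simulated noise was normal and independent between probe sets, with no array set apart, so the figures need not hold for these data.

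The alternatives were leaving out dim probe sets, a second quantile normalization, centring each array on its median, a variance trend with robust moderation, array weights, the letter as a fixed or a random term, 1 probe set per gene, a smaller set of groups in the fit and each array left out in turn. Setting BP array A aside, muscle and pigment scores as covariates, each array left out for the gene lists and each group against sham were added after seeing the data. Permutations, other splits of the animals and, for 2 interactions, moved residuals of the fit without that interaction used fixed seeds. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.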

Results

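Gene expression was measured in mammary gland RNA of 36 female Yucatan miniature pigs aged 5 months, with 1 array per animal and 4 animals in each of 9 groups. The 4 sham-operated pigs kept their ovaries and received saline for 13 days. The other 32 pigs were ovariectomized and received bromocriptine, a dopamine agonist that lowers prolactin secretion, for 8 days. For the last 5 days they received either bromocriptine (groups B, BE, BP and BEP) or haloperidol, a dopamine antagonist that raises prolactin secretion (groups H, HE, HP and HEP). E stands for added estrogen and P for added progesterone. All animals received BrdU, which labels cells that copy their DNA, 24 hours before the end, and BrdU measurements were not used here. The deposited RMA values of 20792 probe sets, read as log2, ranged from 1.552 to 13.74, and the array medians lay between 7.83 and 7.91. Arrays have no read depth, and the number of animals limits the precision. Changes are log2 differences ± SE from limma (n = 4 animals in each group), and folds are those differences on the linear scale.

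The first principal component held 26.0% of the variance and the second 11.6%. HE and HEP arrays lay at the high end of the first component, most arrays without estrogen at the low end, and BE, BEP and sham arrays between them. Array A of group BP stood apart from its group. Its nearest group mean was that of HE, but a foreign nearest group was not peculiar to it. Only 20 of the 36 arrays lay nearest to their own group, and the other BP arrays lay nearest to H or HP. The score of BP array A on the first component was 70.0, where the other BP arrays lay between -65.3 and -48.3. In that animal WAP, a whey protein of milk, was at 12.8, where the other BP animals lay between 5.99 and 9.14 and the HE animals between 12.7 and 13.2. Its skeletal muscle score of 2.97 lay above the range of the estrogen-treated animals, -1.20 to -0.658. All counts were also obtained without that array, an alternative chosen after seeing the data. No pair of arrays was identical, and the highest correlation between 2 arrays was 0.984.

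**Figure D1:**
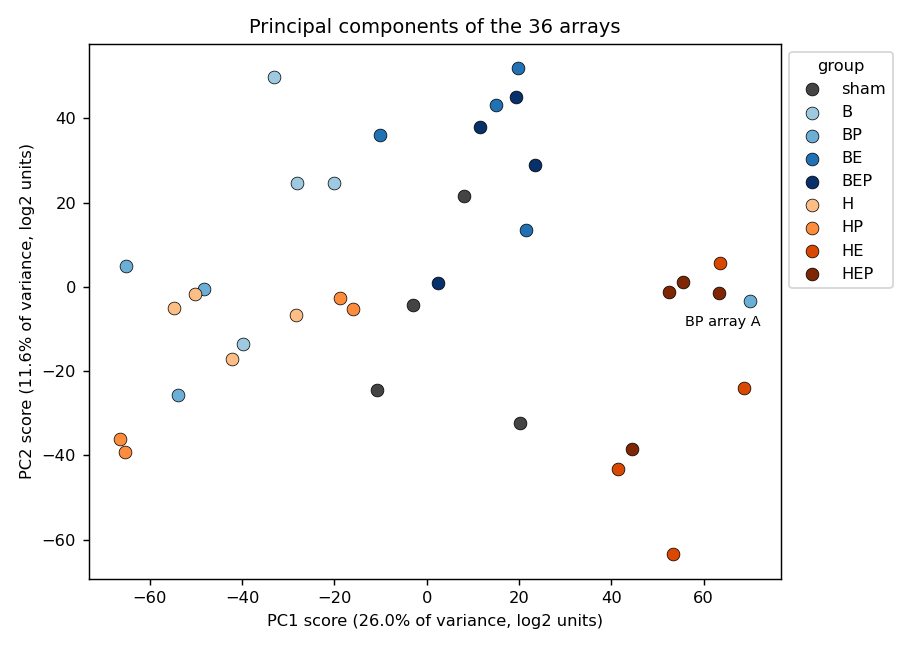
Each point is 1 array, placed by its scores on the first 2 principal components (26.0% and 11.6% of the variance, log2 units) and coloured by group. BP array A, at 70.0 on the first component, lies among the HE and HEP arrays.

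**Figure D2:**
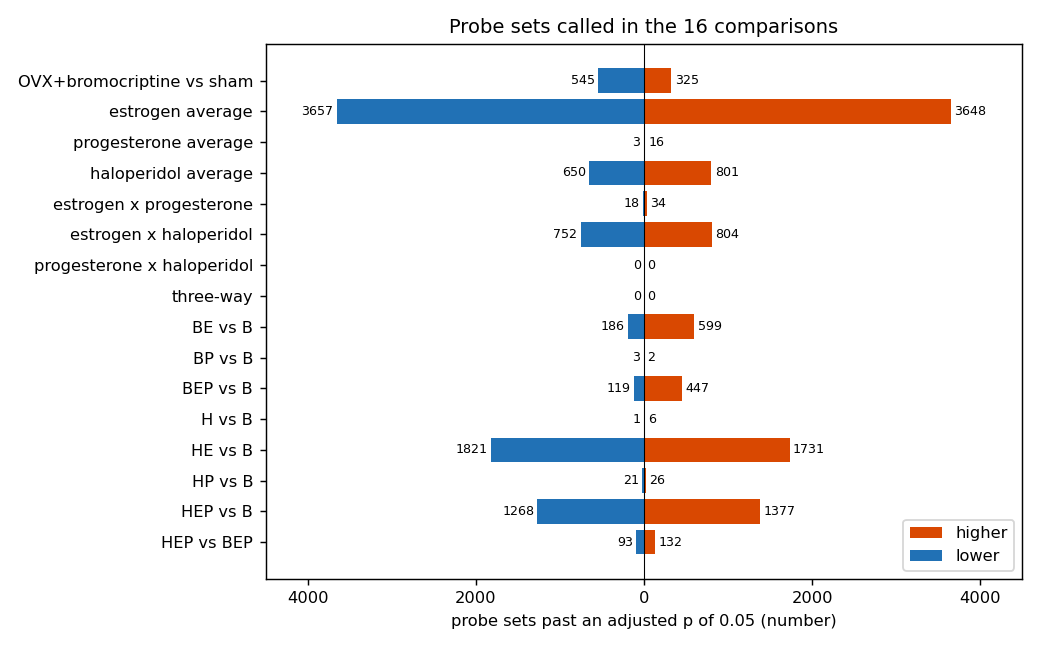
Bars give the number of probe sets past an adjusted p of 0.05 in each of the 16 comparisons, higher to the right and lower to the left. The average effect of estrogen called 7305 probe sets and the interaction of progesterone with haloperidol called 0.

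Group B against sham asks what loss of the ovaries together with bromocriptine changed, and these groups differ in both. Genes of cell division were lower in B: of 36 measured members of the cell cycle list, 28 fell and 0 rose (32 fell when adjusted over the list alone), with a median change of -1.96. RRM2, a subunit of ribonucleotide reductase, fell 13.8-fold (-3.79 ± 0.57, adjusted p = 0.000146), and TOP2A, DNA topoisomerase 2 alpha, fell as well (-3.46 ± 0.64). AREG (amphiregulin), a ligand of the EGF receptor, fell 15.4-fold (-3.95 ± 0.54, adjusted p = 4.9e-05), and each of the 4 B animals was below every sham animal. HAPLN1, a protein that links hyaluronan to proteoglycans, fell 31.1-fold and PGR, the progesterone receptor, fell 5.13-fold (-2.36 ± 0.53, adjusted p = 0.00811). The size of the HAPLN1 fold is uncertain, because its mean in B lay below the lower quartile of every array and detection was not measured. Of 29 genes of fibroblasts and extracellular matrix 5 fell (5 when adjusted over the list alone), among them TNC, or tenascin C (-2.64 ± 0.51), and LOXL1, an enzyme that cross-links elastin (-1.35 ± 0.22). FZD5, a WNT receptor, rose 4.17-fold.

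Milk protein genes varied widely among the B animals: CSN2, beta-casein, was at 10.7 ± 0.30 (SD, n = 4) in sham and at 5.997 ± 4.02 in B. Its change of -4.74 ± 1.36 passed (adjusted p = 0.0413), but not without sham A, B, C or D, or B A, C or D (adjusted p = 0.0533 to 0.183), and without B B it was -6.60. Of 26 milk genes 3 fell (7 when adjusted over the list alone). ESR1, the estrogen receptor alpha gene, differed by 0.04 ± 0.33 (adjusted p = 0.965). Its mean over all arrays, 4.25, lay below the lower quartile of every array. Detection was not measured, so this says little about the gene. Adipocyte markers had a median change of 0.65 (0.38 without B A), with 0 of 16 past the limma test (4 higher when adjusted over the list alone, and 4044 probe sets at an unadjusted p under 0.05 in the whole comparison). Skeletal muscle markers had a median of 1.73, with 0 of 18 past the test and 0 when adjusted over the list alone, and this rested on B A: without it the median was -0.12.

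In all, limma called 325 probe sets higher and 545 lower in B than in sham, a balance that turned with array weights (1534 higher and 1175 lower) and without sham C (672 and 570). Camera called the cell cycle (adjusted p = 5.23e-31), milk (0.000583), adipocyte (0.00231), muscle (0.00231), matrix (0.0161) and endoplasmic reticulum chaperone (0.0109) lists with its preset correlation. None of these calls held with an estimated correlation: for the cell cycle list, adjusted p = 0.125 with an estimated correlation, for the muscle list 0.627, and for the other 4 lists 0.492. With the preset correlation the muscle call was lost without B A (adjusted p = 0.972), the chaperone call without B A (0.0573) and the matrix call without sham C or B D (0.0950 to 0.130). The 870 calls became 522 without sham A, 481 without B C and 424 without sham D.

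The average effect of estrogen compares the 16 animals given estrogen with the 16 ovariectomized animals not given it. All 36 measured cell cycle genes rose (36 when adjusted over the list alone), with a median of 2.02. CCNB1, cyclin B1, rose 12.7-fold (3.66 ± 0.34, adjusted p = 2.85e-09) and TOP2A rose 9.83-fold (3.30 ± 0.32). AREG rose 9.13-fold (3.19 ± 0.27, adjusted p = 2.59e-09), and 13 of the 16 animals given estrogen lay above every animal not given it. AREG was at 6.96 ± 0.99 (SD, n = 4) in B, 10.8 ± 0.47 in BE and 10.9 ± 0.46 in sham. PGR rose 4.80-fold (2.26 ± 0.27), and OXTR, the oxytocin receptor, 3.63-fold. HAPLN1 (2.98 ± 0.34) and HSD11B2, which inactivates cortisol (2.81 ± 0.26), rose too. ESR1 differed by 0.08 ± 0.17 (adjusted p = 0.732), but its mean over all arrays, 4.25, lay below the lower quartile of every array. An effect on ESR1 may thus have been missed.

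Genes of other compartments of the gland moved with estrogen in both directions. Of 29 genes of fibroblasts and extracellular matrix 17 rose and 3 fell (17 and 3 when adjusted over the list alone), with TNC up 6.48-fold, VCAN, or versican, up 2.89-fold and THBS2, or thrombospondin 2, down 2.11-fold. Of 22 endoplasmic reticulum chaperones 9 rose (10 when adjusted over the list alone), among them DNAJB11 and MANF. Of 16 adipocyte markers 11 fell (12 when adjusted over the list alone), among them PCK1, an enzyme of glycerol and glucose synthesis (-1.92 ± 0.31), CFD, or adipsin (-1.85 ± 0.23), and ADIPOQ, or adiponectin (-1.19 ± 0.29, adjusted p = 0.00198). Of 15 endothelial markers 10 fell (11 when adjusted over the list alone), including CLDN5 (-1.39 ± 0.22). Of 18 skeletal muscle markers 13 fell and 1 rose (14 and 1 when adjusted over the list alone), with MYL1, a myosin light chain, down 38.3-fold. The size of that fold is uncertain. The mean of MYL1 over all arrays, 5.13, lay below the lower quartile of every array, and detection was not measured. Single animals without estrogen also had much muscle, such as B A with a muscle score of 5.995. STC1, stanniocalcin 1, fell 5.90-fold (-2.56 ± 0.30, adjusted p = 1.09e-07).

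Milk genes were split: 6 of 26 rose and 1 fell (6 and 1 when adjusted over the list alone), while CSN2 (0.07 ± 0.68, adjusted p = 0.949) and WAP (-0.44 ± 0.75, adjusted p = 0.685) did not pass. Animals B B and BP A, which had unusually high milk transcripts, both belong to the arm without estrogen. The average also joins opposite changes. Without progesterone the mean milk score rose from -1.67 in B to -0.79 in BE and from 0.56 in H to 2.03 in HE. With it the score fell from -0.24 in BP to -1.13 in BEP and from 0.91 in HP to 0.59 in HEP. Luminal epithelial markers had a median of 0.29, with 6 of 20 up and 1 down (9 and 2 when adjusted over the list alone). In all, 3648 probe sets were called higher and 3657 lower, a balance that turned without dim probe sets (2160 higher and 2053 lower) and with 1 probe set per gene (1347 and 1221). Camera with its preset correlation called the cell cycle (adjusted p = 4.65e-32), adipocyte (1.03e-05), endothelial (1.03e-05), muscle (6.39e-05), matrix (0.00221), chaperone (0.014), macrophage and general leukocyte (0.0341) and glucocorticoid (0.0341) lists. None held with an estimated correlation: adjusted p = 0.110 for cell cycle, 0.361 for adipocyte, 0.399 for endothelial, 0.568 for muscle, 0.403 for matrix, 0.568 for chaperone, 0.717 for leukocyte and 0.568 for glucocorticoid genes, each with an estimated correlation. Fry, which does not set a list against the other genes, called each of them. Its adjusted p was 3.09e-10, 6.63e-06, 3.14e-05, 0.00502, 2.93e-06, 7.15e-05, 0.0407 and 0.00318 in the same order. With the preset correlation the leukocyte call was lost without any 1 of 6 arrays (adjusted p = 0.0503 to 0.0681) and the glucocorticoid call without BEP A, H B, HP B or B C (0.0506 to 0.0586).

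**Figure D3:**
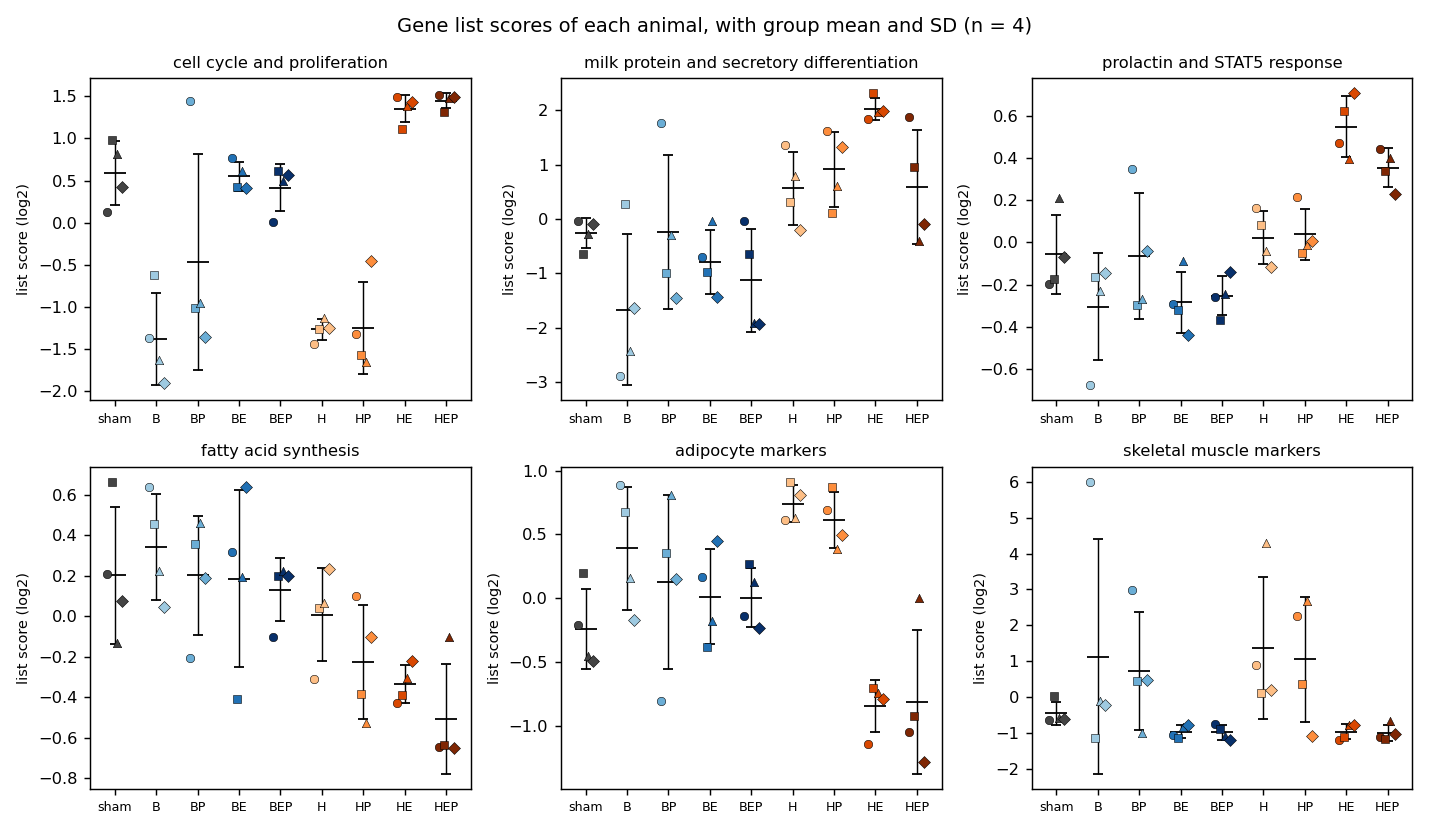
Each panel shows the score of 1 gene list, the mean of its genes on the log2 scale after each gene was centred over the 36 arrays, for every animal, with the mean and SD of each group (n = 4). The mean cell cycle score was -1.38 in B, 0.55 in BE and 1.35 in HE, and the mean milk score was -1.67 in B and 2.03 in HE.

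The average effect of haloperidol compares 16 animals given haloperidol with 16 kept on bromocriptine. Milk genes were higher with haloperidol: 18 of 26 rose and 0 fell (19 rose when adjusted over the list alone), with a median of 1.88. WAP rose 24.6-fold (4.62 ± 0.75, adjusted p = 0.000216), CSN2 rose 13.1-fold (3.71 ± 0.68, adjusted p = 0.000818) and LALBA, the alpha-lactalbumin of lactose synthesis, rose 13.0-fold. These folds depend on unusual animals of the bromocriptine arm. LALBA was at 10.78 in B B, where the other B animals lay between 2.298 and 3.262, and WAP in BP A lay among the HE animals. SLC34A2, a phosphate transporter, rose 21.8-fold (4.44 ± 0.41, adjusted p = 5.72e-08), and all 16 animals given haloperidol lay above the mean of the others. Of 12 genes of the prolactin and STAT5 response 7 rose (8 higher and 1 lower when adjusted over the list alone), among them STAT5A (0.95 ± 0.15, adjusted p = 0.000122) and STAT5B (1.06 ± 0.17). Both rose more in animals given estrogen (interaction 1.06 ± 0.30, adjusted p = 0.0279, for STAT5A and 1.45 ± 0.34, adjusted p = 0.0116, for STAT5B). In H against B STAT5A differed by 0.47 ± 0.30 (adjusted p = 0.586). CSN2 was at 5.997 ± 4.02 (SD, n = 4) in B, 11.8 ± 0.31 in H, 12.3 ± 0.09 in HE and 10.7 ± 0.30 in sham.

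Genes of lipid synthesis were lower with haloperidol: of 16 genes of fatty acid synthesis 7 fell and 1 rose (8 and 1 when adjusted over the list alone). PNPLA3, a lipid droplet enzyme, fell 4.13-fold (-2.05 ± 0.37, adjusted p = 0.000626), ME1, or malic enzyme, 3.15-fold and ELOVL6, a fatty acid elongase, 2.71-fold. GPAM, which starts glycerolipid synthesis, was the member that rose (1.43 ± 0.24). The changes of ELOVL6 and GPAM were larger in animals given estrogen (interaction -1.68 ± 0.42, adjusted p = 0.0153, and 1.91 ± 0.49, adjusted p = 0.0177). ALAS2, the first enzyme of heme synthesis in red cell precursors, fell 5.90-fold (-2.56 ± 0.30, adjusted p = 1.73e-06), and all 16 animals given haloperidol were below the mean of the others. The SLC2A5 fructose transporter fell 2.73-fold and CDO1, or cysteine dioxygenase, 2.37-fold.

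In all, 801 probe sets were called higher and 650 lower with haloperidol, a balance that turned with array weights (1334 higher and 1442 lower). The prolactin and STAT5 list was called with the preset correlation (adjusted p = 4.83e-05), and this call held (adjusted p = 0.0260 with an estimated correlation). It rests on the 12 of 26 listed genes that were measured under their symbol, and CISH, ELF5, PRLR, TNFSF11 and CCND1 were not among them. Camera called the milk list (adjusted p = 1.59e-16) and the fatty acid list (1.51e-06) with the preset correlation but not with an estimated correlation (adjusted p = 0.0676 and 0.0915). Fry called both (adjusted p = 7.35e-06 and 0.000497). The cell cycle, adipocyte, matrix, keratinised skin, hormone receptor and chaperone lists were also called with the preset correlation alone (adjusted p = 0.129 to 0.776 with an estimated correlation). The adipocyte call was lost without any 1 of 16 arrays (adjusted p = 0.0506 to 0.109) and the skin call without B A or HE A (0.0501 to 0.0504). Without BP array A the 1451 calls became 2431. ESR1, which had a low signal and was called lower with haloperidol, lost its call without that array (-0.48, adjusted p = 0.0575).

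The average effect of progesterone was small: 16 probe sets rose and 3 fell. The named genes that rose were HSD11B2 (2.80-fold), DEFB1, or beta-defensin 1 (2.51-fold), FAM3D (2.27-fold), CYP2C33 (2.24-fold), CDA, or cytidine deaminase (1.96-fold), MAL (2.10-fold) and PHGDH, the first enzyme of serine synthesis (0.94 ± 0.13, adjusted p = 0.000354). LRRC43 fell 2.64-fold (-1.40 ± 0.24, adjusted p = 0.00496), and 15 of the 16 animals given progesterone were below the mean of the others. MAL lost its call without 22 of the 32 arrays taken 1 at a time (adjusted p = 0.0506 to 0.0844). Of the 24 lists camera called the cell cycle list, with 0 of 36 members past the limma test and 0 when adjusted over the list alone (median 0.20; 1024 probe sets at an unadjusted p under 0.05 in the whole comparison; adjusted p = 0.596 with an estimated correlation), a call that ended without BP array A (adjusted p = 0.136). The 19 calls became 31 without BP A and 29 without B D.

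The interaction of estrogen with progesterone asks whether progesterone changed the effect of estrogen. PHGDH showed it plainly: the level was 10.4 ± 0.26 (SD, n = 4) in HEP and 8.98 ± 0.47 in BEP, against group means of 7.45 to 7.94 in the other ovariectomized groups and 8.06 in sham. Its estrogen effect was 1.86 ± 0.26 higher with progesterone (adjusted p = 0.000151). The estrogen effects on DEFB1 (2.90 ± 0.50, adjusted p = 0.0031) and CDA (2.18 ± 0.35, adjusted p = 0.00112) were also higher with progesterone. For other genes it was lower: HAPLN1 (-4.54 ± 0.69, adjusted p = 0.00068), LRRC43 (-3.50 ± 0.47), OVGP1, an oviduct glycoprotein (-2.47 ± 0.46), GHRL, or ghrelin (-1.93 ± 0.30), and GSTA1, a glutathione transferase (-1.65 ± 0.29). HAPLN1 was at 9.86 ± 0.48 (SD, n = 4) in BE, 6.13 ± 0.86 in BEP, 3.90 ± 0.43 in B and 8.86 ± 0.74 in sham.

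This interaction called 34 probe sets as higher and 18 as lower. The milk list had a median of -1.35, with 0 of 26 members past the limma test (8 lower when adjusted over the list alone; 2158 probe sets at an unadjusted p under 0.05 in the whole comparison). Camera called it (adjusted p = 1.64e-07) but not otherwise (adjusted p = 0.725 with an estimated correlation), and the same held for the cell cycle, chaperone and immediate early lists (adjusted p = 0.725 to 0.744 with an estimated correlation). With the preset correlation the cell cycle call was lost without BP A (adjusted p = 0.264) and the chaperone call without B A, BP A, HP A or HEP C (0.0633 to 0.188). The 52 calls became 81 without BEP A, 84 without BP C, 33 without H B, 30 without HEP B, 27 without BEP C, 34 without HE C, 32 without HP C and 30 without BE D.

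**Figure D4:**
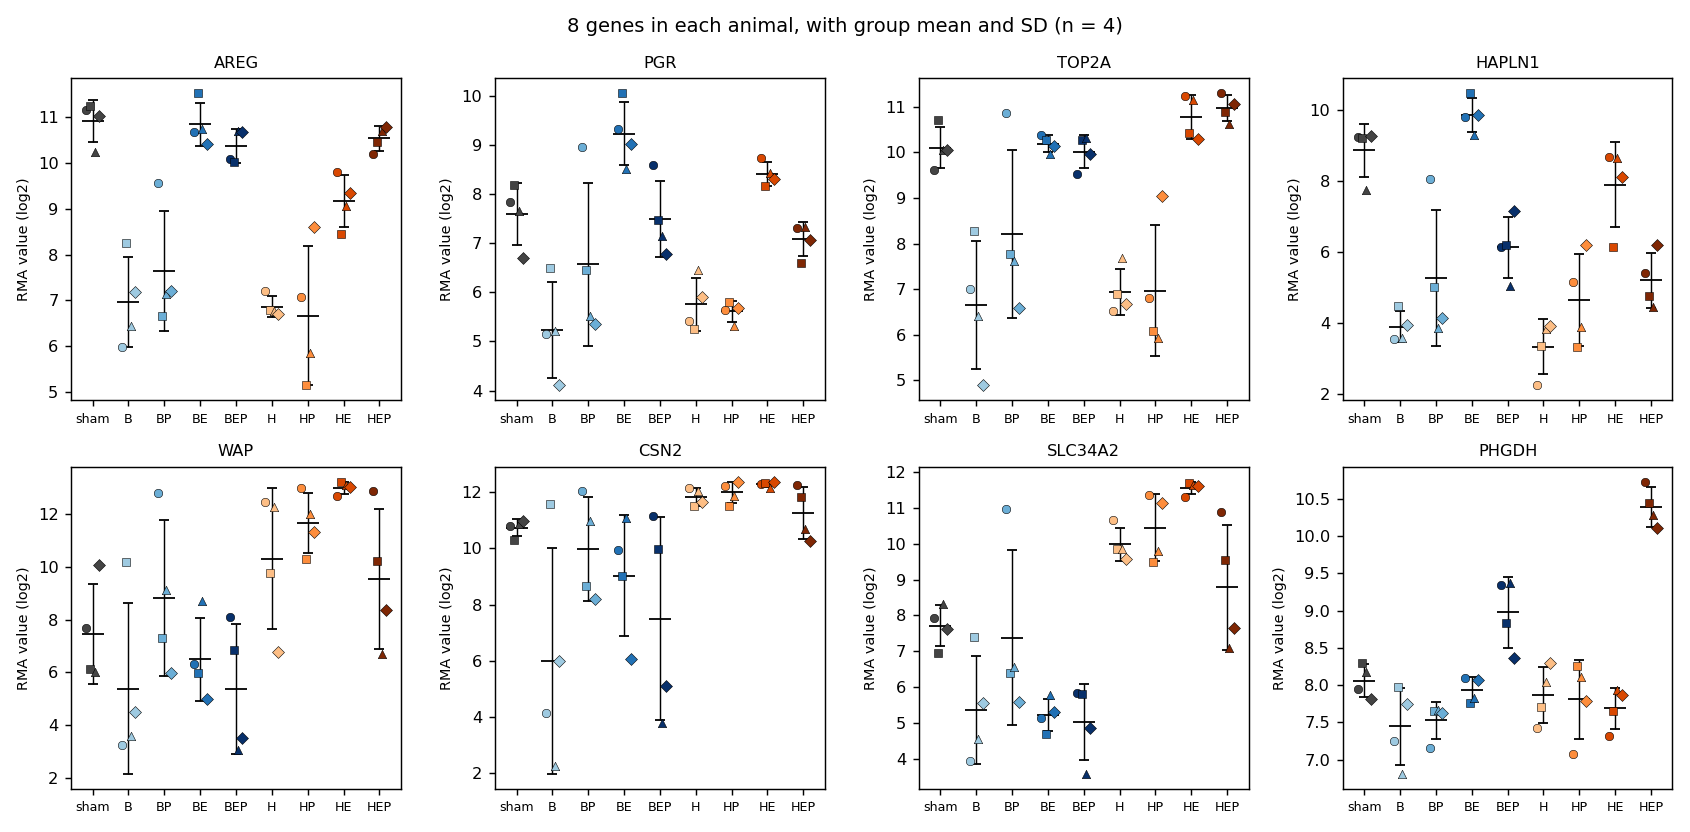
RMA values (log2) of 8 genes in every animal, with the mean and SD of each group (n = 4). PHGDH was at 10.4 in HEP and 8.98 in BEP, and SLC34A2 was at 11.6 in HE and 5.36 in B.

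The interaction of estrogen with haloperidol asks whether the effect of estrogen depended on which dopamine drug was given. FABP7, a fatty acid binding protein, was at 7.79 ± 0.83 (SD, n = 4) in HE and 6.66 ± 1.39 in HEP, and its group means lay between 3.19 and 4.82 in the other groups. Its estrogen effect was 4.91 ± 0.76 higher with haloperidol (adjusted p = 0.000776). ARG2, an arginase (3.33 ± 0.68), HPD, an enzyme of tyrosine breakdown (3.23 ± 0.60), STAT5B (1.45 ± 0.34) and CLDN3, a tight junction protein (1.62 ± 0.34), followed the same direction. Of 36 cell cycle genes 15 had a higher estrogen effect with haloperidol (25 when adjusted over the list alone), with a median of 1.26 and CDCA3 at 2.03 ± 0.54.

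Adipocyte markers had the opposite sign: for 9 of 16 the interaction was called negative (10 when adjusted over the list alone). Among them were PCK1 (-2.81 ± 0.61, adjusted p = 0.008), ADIPOQ (-2.30 ± 0.58, adjusted p = 0.0165) and LIPE, or hormone-sensitive lipase (-2.14 ± 0.55). Negative, or lower below, means a more negative estrogen effect with haloperidol, such as a larger fall or a smaller rise. The mean adipocyte score fell from 0.74 in H to -0.84 in HE, and from 0.39 in B to 0.015 in BE. PCK1 was at 9.51 ± 0.57 (SD, n = 4) in H, 6.41 ± 0.22 in HE, 7.31 ± 1.94 in B and 7.20 ± 0.64 in BE. SCARA5, a ferritin receptor, differed by -3.12 ± 0.68 and SULT1E1, the estrogen sulfotransferase, by -3.35 ± 0.85. Of 29 matrix genes 4 were lower (6 when adjusted over the list alone), with THBS2 at -2.37 ± 0.45. Of 21 macrophage and general leukocyte markers 3 were called lower (7 when adjusted over the list alone): C1QA (-1.10 ± 0.34, adjusted p = 0.0444), C1QC and MRC1. All 3 lost their call without BP A, and each without at least 9 other arrays. Without BP A the changes were -0.98 for C1QA (adjusted p = 0.0816), -0.84 for C1QC (0.0595) and -0.80 for MRC1 (0.0814). Of 15 endothelial markers 2 were called lower (2 when adjusted over the list alone), CLDN5 (-1.53 ± 0.44), lost without BP A (adjusted p = 0.0508) and 6 other arrays, and AQP1 (-1.24 ± 0.37), lost without any 1 of 10 arrays (adjusted p = 0.0523 to 0.0695). The muscle list was not called, and CA3 (-1.22 ± 0.30) was the 1 of its 18 genes that passed (1 when adjusted over the list alone).

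This interaction called 804 probe sets as higher and 752 as lower, a balance that turned without dim probe sets (478 higher and 681 lower) and with array weights (1133 and 1266). Camera called 11 lists, the cell cycle (adjusted p = 5.93e-12), adipocyte (5.46e-07), matrix (9.4e-06), leukocyte (0.00058), glucocorticoid (0.00058), endothelial (0.0098), basal (0.0138), immediate early (0.018), estrogen response (0.0199), prolactin and STAT5 (0.0239) and IGF (0.0394) lists. None of these calls held (adjusted p = 0.248 for cell cycle, 0.193 for adipocyte and matrix and 0.242 to 0.360 for the other genes, with an estimated correlation). With the preset correlation the estrogen response call was lost without B A (adjusted p = 0.0599) and the IGF call without any 1 of 8 arrays (0.0528 to 0.105). The 1556 calls became 1029 without BP array A, of which 1001 were shared, and 19 of 53 named genes lost their call without it. They became 2545 without BP B, 1015 without BEP B, 980 without HP B, 989 without BE D and 1014 without H D.

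For the interaction of progesterone with haloperidol limma called 0 probe sets (971 at an unadjusted p under 0.05; lowest adjusted p = 0.554). The interaction of all 3 factors also had 0 calls with limma (918 at an unadjusted p under 0.05; lowest adjusted p = 0.0661). That count became 4 without BP A, 3 without HP B, 1 without BE C, 1 without BP C, 4 without HP C and 3 without HEP C. Camera called the milk list for progesterone with haloperidol (median -1.002, adjusted p = 4.55e-06, but adjusted p = 0.461 with an estimated correlation), with 0 of 26 genes past the test and 0 when adjusted over the list alone. It also called the cell cycle, endothelial, leukocyte and lymphocyte lists there (adjusted p = 0.461 to 0.874 with an estimated correlation). For all 3 factors it called the cell cycle, basal, interferon, chaperone and immediate early lists (adjusted p = 0.486 to 0.764 with an estimated correlation). With the preset correlation 2 of the former calls were lost: cell cycle without BP A or B D (adjusted p = 0.999 and 0.0674) and lymphocyte without B A (0.0827). Of the latter, the basal call was lost without any 1 of 10 arrays (adjusted p = 0.0504 to 0.178) and the interferon call without any 1 of 6 (0.0521 to 0.227).

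The remaining comparisons set each treated group against B, so 7 of them share the same 4 animals. Of these, animal B A had far more muscle transcripts than the others and animal B B far more milk transcripts: LALBA was at 10.78 in B B and between 2.298 and 3.262 in the other B animals. Without B B the changes of milk genes against B were higher, as for CSN2 in BE, 4.89 against 3.03 (adjusted p = 0.0162, not called with it). Estrogen alone (BE) called 599 probe sets higher and 186 lower than B. PGR rose 15.9-fold (3.99 ± 0.53, adjusted p = 2.59e-05), AREG 14.7-fold, HAPLN1 62.1-fold and LOXL1 2.62-fold, and for these genes each BE animal was above every B animal. The mean of HAPLN1 in B lay below the lower quartile of every array and detection was not measured, so the size of its fold is uncertain. DPP4, a peptidase, fell 4.72-fold and KNG1, or kininogen, 6.67-fold. Cell cycle genes rose in 28 of 36 cases (31 when adjusted over the list alone) and matrix genes in 4 of 29 (7 when adjusted over the list alone). Both lists were called with an estimated correlation (adjusted p = 0.0414 for each), while the estrogen response, milk, basal and muscle lists were called with the preset correlation alone (adjusted p = 0.150 to 0.753 with an estimated correlation). The muscle call was lost without B A (adjusted p = 0.720; median -0.19 against -1.94), and the estrogen response and milk calls without B A or BE C (adjusted p = 0.0638 to 0.505). The 785 calls became 495 without BE A and 443 without BE B.

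Estrogen with progesterone (BEP) called 447 probe sets higher and 119 lower than B. HSD11B2 rose 30.8-fold (4.94 ± 0.52, adjusted p = 1.51e-06), AREG 10.6-fold and CCNB1 10.8-fold, and DPP4 fell 4.23-fold. Cell cycle genes rose in 22 of 36 cases (31 when adjusted over the list alone) and matrix genes in 4 of 29 (11 when adjusted over the list alone), and both lists were called with an estimated correlation (adjusted p = 0.0471 for each). The milk, basal, endothelial, leukocyte and muscle lists were called with the preset correlation alone (adjusted p = 0.308 to 0.611 with an estimated correlation). The muscle (adjusted p = 0.518; median -0.28 against -2.18) and basal (0.116) calls were lost without B A, the milk call without B A, BEP A or B C (0.0594 to 0.334) and the leukocyte call without B A, BEP A, BEP B or B D (0.0660 to 0.334). The 566 calls became 312 without BEP B, 354 without BEP C and 330 without BEP D. Without BP array A, which is in neither group but adds to the estimate of the spread, they became 867.

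Progesterone alone (BP) called 2 probe sets higher and 3 lower than B, and 0 of 13 fixed genes passed limma (2133 probe sets at an unadjusted p under 0.05). The higher were 2 probe sets of 1 transcript with no symbol here (3.11 and 3.19), and the lower were probe sets of DST, or dystonin (-1.68), of LOC100517855 (-0.93) and of a transcript with no symbol here (-1.21), each with adjusted p = 0.0284. They lie outside the rule for named genes and were chosen after their values were seen. WAP differed by 3.44 ± 1.51 (adjusted p = 0.435; 2.10 without BP A and 5.04 without B B) and TOP2A by 1.57 ± 0.64 (adjusted p = 0.402; 0.68 without BP A and 0.98 without B D). Camera called the cell cycle, milk and leukocyte lists with the preset correlation alone (adjusted p = 0.864 to 0.898 with an estimated correlation). Without BP A the cell cycle (adjusted p = 0.0556) and milk (0.213) calls were lost, and the leukocyte call without B A, BP B, BP C, B D or BP D (0.0928 to 0.263). The 5 calls became 0 without B A, B B, B C, BP B or BP D, 9 without B D, 13 without BP C and 19 without BP A.

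Haloperidol alone (H) called 6 probe sets higher and 1 lower than B. SLC34A2 rose by 4.63 ± 0.83 (adjusted p = 0.0274), a call lost without B A, H A, H B or B C (adjusted p = 0.0816 to 0.127). RFLNA rose 3.43-fold (adjusted p = 0.00326, but 0.0553 without B C). CSN2 was higher by 5.83 ± 1.36 and did not pass (adjusted p = 0.104), but it passed without B B (7.69, adjusted p = 0.0045). Macrophage and general leukocyte markers had a median of 0.73, with 0 of 21 past limma (10 higher when adjusted over the list alone; 2191 probe sets at an unadjusted p under 0.05 in the whole comparison). Camera called that list with the preset correlation (adjusted p = 3.19e-09) but not with an estimated correlation (adjusted p = 0.212), and likewise the milk, fatty acid, immediate early and glucocorticoid lists (adjusted p = 0.212 to 0.501 with an estimated correlation). Fry called the leukocyte and milk lists (adjusted p = 0.026 for each) and none of the others (0.0558 to 0.282). The fatty acid call by camera was lost without B A or H A (adjusted p = 0.130 to 0.214). The 7 calls became 1 without B A, H A or H B, 0 without B C, 42 without B D and 34 without BP array A.

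Haloperidol with estrogen (HE) called 1731 probe sets higher and 1821 lower than B, a balance that turned with centring (1800 higher and 1742 lower), a second quantile normalization (1837 and 1712) and 1 probe set per gene (805 and 508). WAP rose by 7.63 ± 1.51 (adjusted p = 0.000645), LALBA by 7.84 ± 1.91 (adjusted p = 0.00444) and CSN2 by 6.28 ± 1.36. No fold is given for these 3 genes because of animal B B, without which the changes were 9.23, 9.85 and 8.14. Milk genes rose in 20 of 26 cases (22 when adjusted over the list alone) and cell cycle genes in 34 of 36 (36 when adjusted over the list alone). Of 22 endoplasmic reticulum chaperones 11 rose and 1 fell (14 and 1 when adjusted over the list alone), and of 16 adipocyte markers 8 fell (9 lower and 1 higher when adjusted over the list alone). STC1 fell 21.3-fold and FOXA1, a partner factor of the estrogen receptor, 4.89-fold (-2.29 ± 0.37, adjusted p = 8.33e-05). Camera called the milk (adjusted p = 2.49e-13), cell cycle (5.86e-31), chaperone (1.84e-05) and adipocyte (2.18e-05) lists, but not with an estimated correlation (adjusted p = 0.107 for the first 3 lists and 0.185 for adipocytes). Fry called each of these lists (adjusted p = 3.38e-06, 7.14e-07, 2.96e-06 and 0.00109 in that order). The prolactin and STAT5, fatty acid, endothelial and muscle lists were also called with the preset correlation alone (adjusted p = 0.107 to 0.671 with an estimated correlation), the muscle list not without B A (adjusted p = 0.478; median -0.27 against -2.06).

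Haloperidol with progesterone (HP) called 26 probe sets higher and 21 lower than B, a balance that turned without B A (9 higher and 13 lower) and without B C (7 and 11). SLC34A2 rose by 5.09 ± 0.83 (adjusted p = 0.00283), ANGPTL4, an inhibitor of lipoprotein lipase, 6.94-fold and MT1A, a metallothionein, 6.88-fold, and FMO5 fell 3.46-fold. WAP was higher by 6.29 ± 1.51 (adjusted p = 0.0689, but 0.0314 without BP array A and 0.0109 without B B). Camera called the milk, fatty acid, leukocyte, interferon and glucocorticoid lists with the preset correlation alone (adjusted p = 0.223 to 0.673 with an estimated correlation). The interferon call was lost without HP A, B C, B D or HP D (adjusted p = 0.0726 to 0.347). The 47 calls became 22 without B A, 117 without HP A, 31 without HP B, 18 without B C, 10 without HP C, 148 without B D and 121 without BP array A.

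Haloperidol with both steroids (HEP) called 1377 probe sets higher and 1268 lower than B, a balance that turned without dim probe sets (784 higher and 791 lower) and with array weights (2010 and 2200). Cell cycle genes rose in 34 of 36 cases (35 when adjusted over the list alone), with NEK2, a mitotic kinase, up 26.5-fold (4.73 ± 0.60, adjusted p = 5.08e-06). Milk genes rose in 14 of 26 cases and fell in 1 (20 and 1 when adjusted over the list alone), with SLC34A2 up by 3.43 ± 0.83. HSD11B2 rose 14.1-fold and TNC 10.7-fold, while SCARA5 fell 9.93-fold, ALAS2 9.28-fold and PNPLA3 11.4-fold. Camera called the cell cycle list (adjusted p = 1.38e-38) and the milk list (5.75e-08), but not with an estimated correlation (adjusted p = 0.0509 and 0.246). Fry called both (adjusted p = 4.02e-07 and 0.00128). The prolactin and STAT5, luminal, adipocyte, fatty acid, endothelial, muscle and chaperone lists were also called with the preset correlation alone (adjusted p = 0.246 to 0.605 with an estimated correlation). Without B A the muscle (adjusted p = 0.398; median -0.27 against -1.96) and prolactin and STAT5 (0.149) calls were lost, as were the luminal call without B A or HEP B (0.0865 to 0.780) and the chaperone call without B A or HEP A (0.195 to 0.236).

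HEP against BEP asks what haloperidol in place of bromocriptine did when both steroids were given. DDC, which makes dopamine from its precursor, rose 5.85-fold (2.55 ± 0.45, adjusted p = 0.00458), RASGRP1 5.48-fold and TMC5 by 2.77 on the log2 scale. NDP, or norrin, fell 4.27-fold (-2.09 ± 0.35, adjusted p = 0.00269), TNXB, or tenascin X, 3.52-fold and ELOVL6 4.50-fold. For each of DDC, NDP and ELOVL6 all 4 HEP animals lay outside the range of the BEP animals. Of 12 prolactin and STAT5 genes 2 rose (6 when adjusted over the list alone), and of 36 cell cycle genes 2 rose (19 when adjusted over the list alone). CSN2 was higher by 3.76 ± 1.36 and did not pass (adjusted p = 0.181). Limma called 132 probe sets higher and 93 lower, a balance that turned without dim probe sets (95 higher and 116 lower) and with array weights (1015 and 1131). Camera called the prolactin and STAT5 list (adjusted p = 0.000486) and the cell cycle list (5.07e-13), but not with an estimated correlation (adjusted p = 0.106 and 0.241), and likewise the milk, adipocyte, fatty acid, matrix and IGF lists (adjusted p = 0.162 to 0.241 with an estimated correlation). Fry called the prolactin and STAT5 list (adjusted p = 0.00073), the matrix list (0.0224), the cell cycle, adipocyte and fatty acid lists (0.0297 for each) and the milk list (0.0376). It did not call the IGF list (0.0926). The IGF call by camera was lost without HEP B (adjusted p = 0.159). The 225 calls became 93 without HEP A, 58 without HEP B, 115 without HEP D, 63 without BEP B, 68 without BEP C, 118 without BEP D and 646 without BP array A, and 20 of 26 named genes lost their call without at least 1 array.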

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

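The counts of other splits and of moved residuals and the tests of the 3 patterns weighed here were chosen after the results were seen, and so was the choice to set BP array A aside.

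BP array A lay far from the other arrays of its group, with a correlation of -0.594 with the mean of the other BP arrays after centring (the others 0.0964 to 0.21) and a first component score of 70.03 (the others -65.27 to -48.32). A swap with an array from an estrogen-treated or sham animal is argued against, because 0 of the 20 arrays of BE, BEP, HE, HEP and sham lay nearest to a group without estrogen. For a response to progesterone shared by the group, 3 of 3 other BP arrays had an estrogen score below the lowest B array. The other BP animals thus did not share the high score, but this largely restates that BP array A stood apart from them, so it is no separate test. It replaced a first one, seen to decide nothing, in which 2 of 7 other BP and HP arrays lay above the highest B or H array. A wrong label or another treatment of this one animal may be the source and cannot be told apart from an unusual BP animal: its estrogen score of 0.538, from 7353 probe sets called without the BP arrays, lay among those of HE (0.375 to 0.541) and far from the other BP arrays (-0.543 to -0.451), and its haloperidol score of 0.353 lay within HE (0.305 to 0.695), but its muscle score of 2.97 lay above all 16 estrogen-treated animals (-1.20 to -0.658). The muscle score was added to this last test after its first result, a label that pointed to this explanation, was seen, and chance alone sets an array apart in about 1 in 20 groups of Dixon's test.

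Skeletal muscle markers were lower on average with estrogen, by 2.04 ± 0.54 in list score, and the animals given estrogen all lay between -1.20 and -0.658, where 13 of 16 ovariectomized animals without estrogen and 4 of 4 sham animals lay above the highest of them. Chance differences in muscle between samples are argued against (permutation p = 2e-05 over 100000 draws within strata, two-sided). A larger epithelial share diluting every other cell type, as the whole cause, is argued against as well, because the differences of 5 cell type scores lay 2.38 ± 0.555 apart, from -2.04 for muscle to 0.339 for fibroblasts. Adipocyte (-0.875 ± 0.14), endothelial (-0.553 ± 0.101) and leukocyte (-0.273 ± 0.105) scores also fell, so dilution as a part of the cause is not excluded. Muscle fibres in the samples, in amounts that differed between treatments, may be the source: within groups without estrogen the median correlation of a marker with the mean of the others was 0.952, and 16 of 18 markers exceeded 0.5. What would make that amount differ with estrogen, such as the size of the gland when it was sampled, was not tested.

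Cell cycle genes were higher on average with estrogen, with a median of 2.02. A higher share of epithelium as the whole cause is argued against, because 15 luminal markers with a mean under 11 had a median change of 0.196 (median absolute deviation 0.208), below 1.01, which is 50% of the cell cycle median. For shifts between arrays left by the normalization, 2649 other genes at the same level had a median change of 0.0271 (median absolute deviation 0.269), also below 1.01. The rise was thus not shared by most genes of that level. This can hardly decide the question, because the nearly equal quantiles of the arrays hold the median of so many genes near zero. The test replaced the centring of arrays, which could hardly move the list because the array medians lay between 7.83 and 7.91. More dividing cells in glands of animals given estrogen remains as a hypothesis that was not itself tested, and the other explanations were weighed on the same data in which the pattern was found.

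Other splits of the same animals were counted for each comparison, with all 35 splits for 2 groups of 4 and 100 for the factorial ones, the real one included. Chance is argued against where 1 split, the real one, gave as many calls: B against sham (870, highest other 320), the averages of estrogen (7305, highest other 1) and haloperidol (1451, highest other 628), BE (785, highest other 48), BEP (566, highest other 5), H (7, highest other 1), HE (3552, highest other 221), HP (47, highest other 9) and HEP (2645, highest other 52) against B, and HEP against BEP (225, highest other 1). That is the smallest share these splits can give, 2.86% with 35 and 1% with 100, and it was not adjusted over the 16 comparisons. For H against B the 7 calls also fell to 1 without B A, H A or H B and to 0 without B C. For the average of progesterone the real split called 19 and the highest other 16, so the real one alone gave as many among 100, by a narrow margin. For the interactions of estrogen with progesterone (52, highest other 5) and with haloperidol (1556, highest other 1) these splits also take away the effect of the moved drug, so they argue only against chance in place of any effect of that drug. With the main effects kept and the residuals of the 32 ovariectomized animals moved instead, 1 of 100 draws, the real one, gave as many for each (48, highest other 25, and 1460, highest other 3). Chance is argued against there, at the smallest share that 100 draws can give. Chance cannot be excluded for BP against B, with 5 calls, where 8 of 35 splits gave as many. Its highest other split called 1469, several times the real count, which points to a structure of the samples: it set BP A with B A, B B and B C against B D and the other BP arrays. Array A alone does not account for it, because without that array the real count was 19 and the highest other split called 407, with 4 of 35 splits as large. For progesterone with haloperidol and for all 3 factors the real count was 0, so 100 of 100 splits gave as many, with highest others of 25 and 109.

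The interactions are differences of effects between groups. Estrogen with progesterone called 52 probe sets, 13 named genes and 4 lists with the preset correlation. Estrogen with haloperidol called 1556 probe sets, 53 named genes and 11 lists. Progesterone with haloperidol and the interaction of all 3 factors each called 5 lists with the preset correlation, and limma called 0 probe sets for both (971 and 918 at an unadjusted p under 0.05). None of these list calls held with an estimated correlation.

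Single animals lay far from the other 3 of their group by Dixon's test in 18 of 216 groups of list scores, where chance gives about 10.8. BP array A did so for cell cycle (1.442, the others -1.35 to -0.9506), EGF family (0.6627), macrophage and general leukocyte (-0.4761) and endoplasmic reticulum chaperone scores (0.1634). B array A did so for skeletal muscle (5.995, the others -1.133 to -0.1123), prolactin and STAT5 (-0.6776) and glucocorticoid scores (-0.4387). HE D had an estrogen response score of 0.2696, sham C a basal and myoepithelial score of 0.5475, sham B a muscle score of 0.03137 and H D a cholesterol synthesis score of -0.01082. Fatty acid scores were -0.1019 in BEP A and -0.1017 in HEP C, and the keratinised skin score was 0.6474 in BEP B. Interferon scores were 0.6016 in B B and 0.4834 in BEP D, and chaperone scores were -0.1355 in BEP D and 0.367 in HEP A.

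Among the fixed genes this was so in 3 of 117 groups of values, where chance gives about 5.85: ESR1 at 4.795 in HE D (the others 3.718 to 3.83), LALBA at 10.78 in B B (the others 2.298 to 3.262) and KRT8 at 11.32 in B A (the others 12.53 to 12.77). Among 2070 groups of values of the other named genes 121 did so, where chance gives about 104.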

How the results depend on the processing

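Setting BP array A aside, using muscle and pigment scores as covariates and leaving out arrays for the gene lists were chosen after seeing the data, and the other alternatives were planned.

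No gene or list called in the main fit was called in the other direction under an alternative in which it was tested again. Genes were not tested again with 1 probe set per gene, a smaller set of groups or the covariates. Lists were tested again only with an estimated correlation, the mean of all probe sets, the letter as a fixed term, centring, BP array A set aside and each array left out. Of 664 gene results 498 were called, and 165 of these lost the call without at least 1 array. Of 384 list results 99 were called with the preset correlation, and 94 of these were not called with an estimated correlation, while 34 of the 99 were lost without at least 1 array. Gene calls were gained and lost as follows: 14 and 9 with array weights, 2 and 5 with arrays centred on their median, 0 and 10 with a second quantile normalization, 0 and 4 with a variance trend, 1 and 2 without dim probe sets (448 results measured), and 6 and 21 with BP array A set aside. List calls gained and lost were 12 and 3 with the mean of all probe sets of a gene, 0 and 2 with centring, and 11 and 9 with BP array A set aside. Where a count moved, the cause was not tested, except that leaving out dim probe sets or keeping 1 probe set per gene leaves fewer to call where a count fell.

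Counts of called probe sets that moved by over 1.5 times, or to or from 0, are given here. Without dim probe sets they were 450 for B against sham, 4213 for estrogen, 7 for progesterone, 929 for haloperidol, 12 for estrogen with progesterone, and against B 448 for BE, 0 for BP, 297 for BEP, 3 for H, 2084 for HE, 13 for HP and 1575 for HEP. With 1 probe set per gene they were 299 for B against sham, 2568 for estrogen, 8 for progesterone, 628 for haloperidol, 14 for estrogen with progesterone, 706 for estrogen with haloperidol, 1 for all 3 factors, 284 for BE, 0 for BP, 222 for BEP, 1313 for HE, 25 for HP, 996 for HEP and 137 for HEP against BEP. With array weights, from 0.208 for BP array A to 2.29, they were 2709 for B against sham, 44 for progesterone, 2776 for haloperidol, 162 for estrogen with progesterone, 2399 for estrogen with haloperidol, 4 for all 3 factors, 1898 for BE, 0 for BP, 1185 for BEP, 104 for H, 4210 for HEP and 2146 for HEP against BEP. With only the 2 groups compared in the fit they were 249 for B against sham, 502 for BE, 0 for BP, 338 for BEP, 2298 for HE, 1 for HP and 455 for HEP against BEP, and with only the 32 ovariectomized animals 1 for all 3 factors. With BP array A set aside they were 31 for progesterone, 2431 for haloperidol, 1029 for estrogen with haloperidol, 4 for all 3 factors, 19 for BP, 867 for BEP, 34 for H, 121 for HP and 646 for HEP against BEP. With muscle and pigment scores as covariates they were 0 for BP, 0 for H and 9 for HP. A second quantile normalization gave 3 for BP (2 higher, 1 lower, against 2 and 3), and a variance trend gave 2 for BP and 3 for all 3 factors. Centring moved none.

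Which direction had more calls turned in several comparisons. Higher and lower calls were 2160 and 2053 for estrogen, 478 and 681 for estrogen with haloperidol, 784 and 791 for HEP and 95 and 116 for HEP against BEP without dim probe sets. With array weights they were 1534 and 1175 for B against sham, 1334 and 1442 for haloperidol, 1133 and 1266 for estrogen with haloperidol, 2010 and 2200 for HEP and 1015 and 1131 for HEP against BEP. With 1 probe set per gene they were 1347 and 1221 for estrogen and 805 and 508 for HE, with centring 3727 and 3587 for estrogen and 1800 and 1742 for HE, and with a second quantile normalization 1837 and 1712 for HE. With a variance trend they were 3700 and 3655 for estrogen, 809 and 859 for estrogen with haloperidol and 2 and 0 for BP, with the 2 groups alone 1153 and 1145 for HE, and with the letter as a fixed term 2 and 1 for BP.

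With each array of the groups compared left out in turn, counts ranged from 424 to 1276 for B against sham, 6615 to 8668 for estrogen, 18 to 31 for progesterone, 1066 to 2431 for haloperidol, 27 to 84 for estrogen with progesterone, 980 to 2545 for estrogen with haloperidol, 0 to 4 for all 3 factors, 443 to 825 for BE, 0 to 19 for BP, 312 to 519 for BEP, 0 to 42 for H, 2792 to 3493 for HE, 10 to 148 for HP, 1851 to 2565 for HEP and 58 to 197 for HEP against BEP. For progesterone with haloperidol limma called 0 throughout, against 971 at an unadjusted p under 0.05.

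The letter as a fixed term gave 3 for BP, 4 for H and 2 for all 3 factors, gained 2 and lost 11 gene calls and gained 3 list calls, and moved no other count by over 1.5 times. As a random term (correlation 0.0233) it gave 11 for H and gained 2 gene calls. Over 144 pairs of arrays of 1 letter, the median correlation of deviations from the group mean was 0.0453 (-0.414 to 0.457), 52 pairs exceeded 0.1, pairs of another letter and group had a median of -0.0174, and 14 of 36 arrays correlated best with their own letter. This is a hint from the data and says nothing of the design.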

Other observations

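The comparisons of each group with sham, the test of milk genes in HEP against HE and the comparison of score changes with 50% of a gene's change were chosen after results had been seen.

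Set against sham animals, the groups differed in how many probe sets limma called. B had 870 and H 841, HE 750 and HP 571, while BE had 131, HEP 152, BEP 34 and BP 27. Without BP array A these became 1247 for B, 1255 for H, 1474 for HE, 945 for HP, 250 for BE, 723 for HEP, 89 for BEP and 798 for BP. The differences between these counts were not tested. The mean cell cycle score was 0.59 in sham, 0.55 in BE, 0.42 in BEP, 1.35 in HE and 1.45 in HEP, and the mean milk score was -0.26 in sham and -0.79 in BE.

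Cholesterol synthesis and interferon genes were measured beside the lists described so far. With estrogen 6 of 13 genes of cholesterol synthesis rose and 1 fell (6 and 1 when adjusted over the list alone), among them SQLE, or squalene epoxidase (0.75 ± 0.22, adjusted p = 0.00722), and FDPS, or farnesyl diphosphate synthase (0.92 ± 0.18, adjusted p = 0.000249). Of 17 interferon-stimulated genes 5 fell and 1 rose with estrogen (7 and 1 when adjusted over the list alone), with IFIT2 at -0.96 ± 0.18 (adjusted p = 0.000107). Neither list was called by camera (adjusted p = 0.173 and 0.0763). TYRP1, an enzyme of melanin synthesis, was higher in HEP than in B by 5.54 ± 1.65 (adjusted p = 0.0235), a call lost without B A, HEP B, HEP C or B D (adjusted p = 0.0524 to 0.0657), and its SD within groups reached 3.70.

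As a hypothesis, progesterone may lower milk genes where estrogen and haloperidol are present: the milk score was 1.45 lower in HEP than in HE. The exact permutation p was 0.0571 over 70 splits (two-sided, 4 animals against 4), 22 of 26 genes were lower and 1 passed limma, among 99 probe sets called. The hypothesis remains open, because a p above the threshold does not show that the groups were alike.

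The next 3 hypotheses were written before their tests were seen. PHGDH was higher with progesterone, so other enzymes of serine, glycine and one-carbon metabolism might rise too; 0 of 16 measured members passed limma and the median was -0.04 (camera p = 0.965 with an estimated correlation). ALAS2 was lower with haloperidol, so fewer red cell precursors might be present; of 10 measured red cell genes AHSP fell and the median was -0.08 (camera p = 0.0710 with an estimated correlation). ATP6V0D2 was higher in HEP than in BEP, so other subunits of the vacuolar proton pump might rise too; ATP6V1C2 rose, among 16 measured, and the median was 0.02 (camera p = 0.712 with an estimated correlation). A p of 0.05 or more had been written down as the result that would count against each, and the size of each change was compared afterwards with 50% of that of the gene that raised the question. For the one-carbon enzymes (score change -0.0171 ± 0.0491, 95% limit 0.0837, against 0.470) and the pump subunits (0.133 ± 0.0925, limit 0.323, against 1.94) a rise of the whole set by 50% of that gene's change is argued against, although ATP6V1C2 rose alone. A smaller rise, up to these limits, is not excluded. The red cell hypothesis stays open: the score change of -0.155 ± 0.0489 was far smaller than -1.28, 50% of that of ALAS2, but it was downward, AHSP fell, and the list had camera p = 0.0445 with the preset correlation.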
